A study of Nicotiana tabacum with 30 samples.

How the data were processed

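Total RNA was extracted from mature tobacco leaves, and 30 libraries were sequenced, 3 from each of 10 plant materials. Per the labels' protocols, RNA was extracted with TRIzol and treated with DNase I, and paired-end libraries were built with an Illumina TruSeq kit. Per the submitters' processing notes, HISAT2, StringTie and RSEM were used, in an order and with versions and settings that are not given in the sources used here. The genome build and the gene annotation are not named in those notes, but the gene identifiers in the expression table start with Nitab4.5.

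Each library was assigned to its line or hybrid, and given its replicate number, from its sample title. The expression values come in 1 table for the whole series, which lists 69500 gene identifiers. Its 30 columns of values are headed by a letter joined to a numeric code, with 10 codes and 3 letters for each code. The column names and the codes were searched for in every sample's title, source name, description and characteristics with Python 3.11.15, and 0 of the 30 columns matched a label. Assigning columns to lines by their order, or by the expression of particular genes, would have been a guess, so all 30 columns were left out and no expression value enters the text. The unit of the deposited values was not checked against the values. The depth of the libraries is not given in the sources used here and was not computed.

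The gene identifiers were compared with the gene IDs, locus tags, symbols, synonyms and accessions of a RefSeq gene table for the tobacco cultivar K326, assembly ASM71507v2, and 0 of the 69500 were found there, since none of these fields holds a Nitab4.5 identifier. That table holds no product descriptions, so the 26 gene lists fixed before the data were examined, among them lignin synthesis, xylem, phloem, auxin response, photosystems and nitrate assimilation, could not be filled.

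Each hybrid was to be compared with its female parent, its male parent and the mid-parent value, and its parents with each other, within the 9 libraries of the cross. The 31 results planned before the data were examined also covered genes outside the range of both parents, gene list tests, overlaps between crosses without a shared parent, and differences of the mid-parent deviation between crosses with one. None was computed, because each needs libraries of known identity.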

Results

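The study profiled gene expression in mature leaves of Nicotiana tabacum, the cultivated tobacco, by RNA sequencing, to compare hybrids with their inbred parents in relation to the vein ratio of the leaf. The 30 libraries came from 10 plant materials, each with 3 replicates. The design text of the series instead speaks of 9 samples from 3 plant materials, a number that fits 1 hybrid with its parents but not the 30 samples listed, and the groups here follow the sample labels. The labels do not say whether the replicates of a material came from separate plants.

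The materials were 6 inbred lines and 4 hybrids. G70 was the female parent of 2 hybrids, G70×Qinggeng and G70×Basma, whose male parents were Qinggeng (titled Qing) and Basma. K326 was the female parent of K326×TN90 and GDH94 that of GDH94×TN90. TN90 is labelled as the male parent of GDH94×TN90, and the name of K326×TN90 gives it as a parent of that hybrid as well. K326 is a flue-cured cultivar, TN90 a burley and Basma an oriental tobacco.

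Each hybrid forms a set of 9 libraries with its parents. In each of the 4 crosses, the design thus allows the hybrid to be compared with either parent and with the mid-parent level. It also allows the parents to be compared with each other. G70 and TN90 each serve in 2 crosses, so the comparisons within those pairs of crosses would share the 3 libraries of that parent.

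The expression table lists 69500 tobacco gene identifiers with 30 columns of values, the same number as the libraries. The columns carry 10 codes with 3 letters for each code, and 0 of the 30 column names or codes occurred in a sample label. No column could therefore be assigned to a line or hybrid. No difference between a hybrid and its parents was tested, and no gene is reported as higher or lower in any of the 10 materials.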

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

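Both searches were repeated more loosely, in ways chosen after seeing the data. With the numeric code looked for anywhere in any label, protocols included, 0 of the 30 columns matched. With the gene identifiers compared in any letter case, with or without their prefix, 0 of the 69500 were found in the RefSeq gene table. This search compared names only, so it cannot show whether the same genes are present there under other identifiers. No paired analysis was possible because no column was assigned to a line, so there was no comparison between groups for a replicate block to enter. Whether columns that share a letter resemble each other was not examined. The settings listed before the data were examined (another pseudocount, other filters on low values, the count-based tests, all 30 libraries in one fit, a fold threshold, a linear mid-parent, an estimated inter-gene correlation and leaving out each library) were not run, since no comparison between groups was computed. What the sequencing depth limits was not assessed.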
